A study of Mus musculus with 8 samples.

How the data were processed

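Testis RNA of adult C57BL6-background Exd2∆ and Exd2+/+ mice was profiled by small RNA-seq and long RNA-seq, with 2 replicates per genotype and assay (8 libraries). Per the labels' protocols, small RNA was cut from a gel loaded with 10 µg of total RNA, long RNA libraries were made from 1 µg of total RNA after rRNA depletion with a directional kit, and both were sequenced single-end to a read length of 50 nt. The submitters' design text calls the replicates biological.

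The authors deposited, for each assay, a table of estimated counts per piRNA locus and library for the same 208 loci. These deposited estimated counts are not scaled to library size and need not be whole: all are multiples of 1/2520 (2520 times the value lies within 0.001 of a whole number), and 1.44% to 3.37% of the values in a small RNA library and 10.1% to 14.4% in a long RNA library are whole. Splitting a read evenly among up to 10 alignments would give such fractions, so counts of loci with repeated sequence are less certain. Each table also holds the authors' log2 fold change and, per the file headers, an adjusted p-value from edgeR. Per the submitters' processing notes, cutadapt, STAR and edgeR were used with the GRCm38 build; their versions, the counting tool, its strand setting and its handling of multiple alignments are not given in the sources used here. The loci 15-qD3-14639.3 and pi-1700016M24Rik.2 overlap by 384 bp on opposite strands, and their counts in this stretch can be told apart only if counting used strand. Columns were matched to samples by the sample codes in the labels, and 0 columns were left unmatched.

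Loci were placed on GRCm38 by the coordinates in the tables and compared with the GENCODE M21 annotation. Of the 114 loci named for a gene, 105 overlap the gene of that symbol on the same strand, 7 a gene with that older symbol, and 2 were not matched. Of the 94 band-named loci, 26 overlap no annotated gene on their strand. Exd2 and Exd1 overlap none of the 208 loci, so the planned check of the targeted gene was not analysed here, nor were markers of testis cell types or of transposons.

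Estimated counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr, which kept all 208 loci in both assays, TMM scaling within the table, estimateDisp, glmQLFit and glmQLFTest with genotype as the only term), separately per assay. P-values were adjusted by the Benjamini-Hochberg method over 208 loci, and a locus was called at an adjusted p below 0.05. The standard error of a log2 fold change is its absolute value divided by the square root of the F statistic. CPM are scaled by TMM. The interaction of assay and genotype was tested in 1 edgeR fit of all 8 libraries with TMM factors from within each assay. Groups of loci (21 groups with at least 5 members: name class, listed precursor bands, strand and chromosome) were tested with camera (preset correlation 0.01, and estimated) and fry from limma 3.58.1. Correlations across loci and differences of medians used 100000 permutations, two-sided.

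The quasi-likelihood fit used the legacy option of glmQLFit, a choice made after the first results were seen. With the default option of this edgeR version, the working dispersion of the small RNA fit fell to 6.24e-05, and edgeR's residual deviances then departed by more than 10% from the closed form of the negative binomial deviance at 115 of 208 loci (by up to 2.60e+06-fold), with a negative F at 4 loci. With the legacy option 0 loci departed in either assay and no F was negative. The default option gave 130 calls in small and 14 in long RNA. In long RNA the default option showed no such departure (0 loci), and the legacy option was used there only to treat both assays alike. That raised the long RNA calls from 14 to 16, adding 11-qB1.3-590.3 and 5-qG3-23659.2 (adjusted p = 0.0515 each by default), and the loci called in opposite directions from 11 to 12.

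Tests, groups, the rule for named loci and most alternatives were fixed before the data were examined. The rule named, per assay, all called loci of a direction if at most 10, otherwise the 10 with the largest fold change among those whose Exd2∆ libraries lie on 1 side of both Exd2+/+ libraries; the 10 most abundant loci; the 5 largest rises and 5 largest falls above the median abundance; and up to 4 examples of each group. It named 39 loci in small and 27 in long RNA. The alternatives were RLE and library-total scaling, no filter and a filter of at least 100 counts in 2 libraries, DESeq2 1.42.0, edgeR's exact test, limma-voom, the replicate number as a block, an adjusted p below 0.1, an absolute log2 fold change above 1, and leaving out each library in turn. Alternatives planned for normalized values were not needed.

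The fits were tested on simulated counts drawn with the means, library sizes and dispersions of the real loci, with 60 of 208 loci changed, in 20 simulations. In small RNA 64.0%, 94.0% and 100% of loci changed by 1.25-, 1.5- and 2-fold were recovered, in long RNA 29.5%, 86.8% and 99.5%, and for the interaction 19.2%, 65.2% and 97.8%. On average 1.65, 1.40 and 1.40 unchanged loci were called. With the 35 listed loci lowered by 1.25-fold in long RNA, camera called them in 100% of simulations with the preset correlation and in 0% with an estimated correlation. Loci were drawn independently, with 1 dispersion per locus for both genotypes. In the data the Exd2∆ replicates differed more from each other than the Exd2+/+ replicates, so these rates hold only for the simulated setting.

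Each replicate counted as 1 sample, since the submitters call the replicates biological. The labels do not say whether each came from a separate animal, so p-values measure the spread between these samples. The replicates of a group were compared only to see whether 1 library was deposited under both numbers, and their counts differed by more than sampling noise in every group (chi-square per degree of freedom 114 and 425 in small RNA and 20.1 and 95.8 in long RNA, Exd2+/+ and Exd2∆). The labels give no batch, so library preparation and genotype cannot be separated.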

Results

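The study asked whether the loss of part of Exd2, which encodes an exonuclease domain-containing protein, alters the production of PIWI-interacting RNAs (piRNAs) in the mouse testis. Exd2∆ mice carry a genome-edited deletion that removes the end of exon 2 and part of the following intron. Testis RNA from 2 adult Exd2∆ and 2 Exd2+/+ replicates, which the labels call biological, was sequenced as small RNA, which holds the mature piRNAs, and as rRNA-depleted long RNA, which holds the piRNA precursors and, at loci over protein-coding genes, can hold their mRNA. The word precursor stands for all long RNA counted at a locus. Likewise, the word piRNA stands for all small RNA counted at a locus. Both assays were counted over the same 208 piRNA loci, of which 114 are named for a gene (for example pi-Ip6k1.2) and 94 for a chromosome band (for example 17-qC-935.1). The small RNA libraries held 28408830 and 33983711 estimated counts over these loci in Exd2∆ and 29039671 and 37660202 in Exd2+/+. The long RNA libraries held 960909 and 1638327 in Exd2∆ and 1406947 and 1842625 in Exd2+/+. The least covered locus had 86.8 counts in a small RNA library and 14 in a long RNA library, for a counting error of 10.7% and 26.7%. The labels name no molecular identifiers, so these errors cover counting only. Exd2 itself (GRCm38 chromosome 12, 80463095 to 80500227, plus strand) lies outside the 208 loci, and its level was not analysed here, so the genotype labels rest on the submitters' descriptions. CPM are counts as a share of the library total, scaled by TMM. All values are relative to the sum over the 208 loci, and a change shared by all of them would not be seen.

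In Exd2+/+ testis most piRNA counts came from the band-named loci, many of which are long intergenic precursors of the pachytene stage of meiosis. The 94 band-named loci took 96.6% ± 0.0616 of the small RNA counts in Exd2+/+ and 96.9% ± 0.160 in Exd2∆ (SD, n = 2 each). In long RNA they took 66.5% ± 0.358 in Exd2+/+ and 62.4% ± 2.22 in Exd2∆ (SD, n = 2 each). The 10 most abundant loci held 43.7% ± 0.0710 of the small RNA counts in Exd2+/+ and 44.5% ± 1.37 in Exd2∆ (SD, n = 2 each), a difference within the spread of the Exd2∆ libraries.

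piRNAs from individual loci differed between the genotypes in both directions. Of the 208 loci, 69 were higher and 66 lower in Exd2∆ (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), and 73 were not called. As fold changes are relative to these loci, scaling helps set this balance. The share of calls that were higher was 51.1%, against 47.0% with RLE and 54.1% with library-total scaling. The falls were the larger changes, with 20 loci lower by more than 2-fold and 1 locus, pi-Hjurp.2, higher by more than 2-fold. The deepest fall was at pi-Fam53b.1 (chromosome 7, 132712087 to 132852628, minus strand, over the protein-coding gene Fam53b), from 155 ± 8.99 to 24.1 ± 2.01 CPM (SD, n = 2 each), a log2 fold change of -2.68 ± 0.14 (SE; adjusted p = 4.77e-07, edgeR quasi-likelihood). The median of the absolute log2 fold changes over all loci was 0.34.

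Among the loci with the largest falls, several lie over protein-coding genes. pi-Ip6k1.2, over a gene for an inositol phosphate kinase, fell by 2.20 ± 0.14 on the log2 scale, from 84.2 ± 0.480 to 18.3 ± 2.05 CPM (chromosome 9, 107995742 to 108048780, plus strand). pi-Mgll.2, over the monoacylglycerol lipase gene, had a log2 fold change of -1.47 ± 0.16. pi-Dnmt3a.2, over the gene for a de novo DNA methyltransferase, stood at -1.46 ± 0.12. pi-Lsmd1.1 (-1.68 ± 0.14), pi-Zfp346.2 (-1.38 ± 0.14) and pi-Hist1h1a.2 (-1.38 ± 0.11), the last over a histone gene, were lower as well. Abundance was low at pi-Lsmd1.1 (12.1 to 3.75 CPM), pi-Hist1h1a.2 (14.2 to 5.43 CPM) and pi-Dnmt3a.2 (15.2 to 5.53 CPM). Of the band-named loci, 17-qC-935.1 fell from 1700 ± 233 to 403 ± 39.6 CPM, 13-qA5-967.1 from 1839 ± 103 to 484 ± 49.1 CPM and 13-qA3.1-355.1 from 440 ± 23.9 to 122 ± 3.39 CPM (SD, n = 2 each). The last 3 had log2 fold changes of -2.08 ± 0.10, -1.93 ± 0.08 and -1.85 ± 0.10. The adjusted p of these 9 loci was at most 4.07e-05 (edgeR quasi-likelihood).

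The rises were smaller. pi-Hjurp.2, over the gene for a chaperone of the centromeric histone variant (chromosome 1, 88258855 to 88277518, minus strand), rose from 20.9 ± 7.02 to 75.8 ± 16.1 CPM (log2 fold change 1.86 ± 0.23, adjusted p = 1.17e-04, edgeR quasi-likelihood). pi-Gabpb2.1 (1.00 ± 0.15) and pi-Elk4.1 (0.92 ± 0.13), over genes for transcription factor proteins, also rose, as did pi-Rad54l2.1 (0.88 ± 0.11, from 9.33 to 17.1 CPM), pi-Rnf169.1 (0.72 ± 0.14), pi-Zyg11b.1 (0.70 ± 0.13) and pi-Cbx5.3 (0.69 ± 0.12), the last over the gene for a heterochromatin protein. Among the band-named loci, 7-qF3-246.1 (0.79 ± 0.11), 7-qD1-654.1 (0.77 ± 0.07) and 4-qB3-3994.3 (0.74 ± 0.06) rose. 10-qB4-6488.2 rose from 11832 ± 181 to 17652 ± 28.8 CPM (0.58 ± 0.05), and 19-qC2-1361.2 (0.68 ± 0.07), pi-Ccdc117.1 (0.52 ± 0.09) and 7-qD1-9417.1 (0.52 ± 0.06) were higher too. The adjusted p of these loci was at most 0.00169 (edgeR quasi-likelihood).

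Of the 10 loci richest in piRNAs, 7 were not called. Only 17-qA3.3-26735.1 (48559 ± 399 to 34991 ± 333 CPM, log2 fold change -0.47 ± 0.06, adjusted p = 1.02e-04), 14-qA3-19970.2 (-0.23 ± 0.06, adjusted p = 0.00878) and 12-qE-23911.2 (0.20 ± 0.07, adjusted p = 0.0323) passed the edgeR quasi-likelihood test. The call of 12-qE-23911.2 was lost without Exd2∆ replicate 1 (0.11, adjusted p = 0.130, edgeR quasi-likelihood) and without either Exd2+/+ replicate (0.17 and 0.23, adjusted p = 0.315 and 0.159), and also with DESeq2 and edgeR's default option (adjusted p = 0.0567 and 0.134). That of 14-qA3-19970.2 was lost without either Exd2+/+ replicate (-0.24 and -0.22, adjusted p = 0.0902 and 0.129). The most abundant locus, 18-qE1-36451.1, measured 60960 ± 207 CPM in Exd2+/+ and 68780 ± 5483 CPM in Exd2∆ (SD, n = 2 each; adjusted p = 0.0599). 2-qE1-35981.2 (-0.05 ± 0.08), 9-qC-31469.1 (-0.15 ± 0.07), 6-qF3-28913.1 (0.06 ± 0.07), 5-qG3-23659.2 (0.08 ± 0.08), 7-qD2-24830.3 (-0.03 ± 0.07) and 9-qA5.3-24188.1 (0.08 ± 0.08) were not called. The sign of each of these 6 but 9-qC-31469.1 turned without 1 of the Exd2∆ replicates. Of the 2 gene-named loci with the highest mean small RNA CPM over all 4 libraries, pi-Gm5878.1 fell by 0.69 ± 0.06 (adjusted p = 6.75e-06, edgeR quasi-likelihood). The other, pi-Tmem194.3, stood at 0.12 ± 0.07 (adjusted p = 0.192, edgeR quasi-likelihood) and at -0.01 without Exd2∆ replicate 1.

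No class of locus stood apart from the rest in small RNA. Of the 35 loci that match a list of 16 well-known piRNA precursor bands, 10 rose, 8 fell and 17 were not called, and the counts were the same when adjusted over the list alone. Of the 114 gene-named loci 39 rose and 31 fell (37 and 31 adjusted over the list alone), and of the 94 band-named loci 30 rose and 35 fell (30 and 35 adjusted over the list alone). Camera called 0 of the 21 groups tested (name class, the listed loci, strand and chromosome; lowest adjusted p = 0.379 with the preset correlation, 0.913 with an estimated correlation), with 1 group, chromosome 13, at an unadjusted p under 0.05. The fry test of movement in 1 direction called 8 groups and its test of change in either direction all 21, and neither compares a group with other loci. The median of the gene-named loci was 0.05 and their mean -0.06, so the sign of their centre depends on the summary. At scaling to the library total the median log2 fold change over all loci was 0.08 (0.02 to 0.11 over the 4 pairs of an Exd2∆ and an Exd2+/+ library), and with TMM 0.04.

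**Figure D1:**
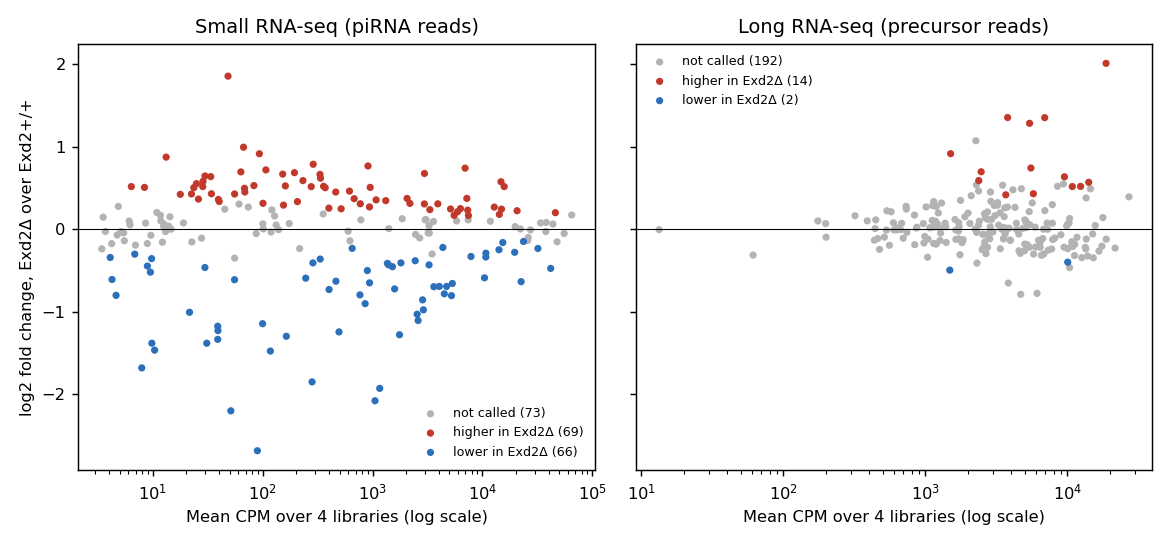
Log2 fold change of Exd2∆ over Exd2+/+ (vertical axis) against mean CPM over 4 libraries (horizontal axis, log scale) for the 208 piRNA loci, in small RNA (left) and long RNA (right). Each point is a locus, red where higher and blue where lower in Exd2∆ at an adjusted p below 0.05. In small RNA 69 loci were higher and 66 lower, and in long RNA 14 were higher and 2 lower.

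Fewer loci were called in long RNA. There 14 loci were higher and 2 lower in Exd2∆, and 192 were not called (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). DESeq2 called 39 (28 higher, 11 lower), edgeR's exact test 25 (20 and 5), and an adjusted p below 0.1 gave 26 (21 and 5), so the number of calls, and of falls most of all, depends on the tool and threshold. The largest rise was at 17-qC-935.1 (chromosome 17, 49112270 to 49113511, minus strand, within the lincRNA gene 1700008K24Rik), from 7432 ± 533 to 29965 ± 7691 CPM (SD, n = 2 each), 4.03-fold (log2 fold change 2.01 ± 0.19, adjusted p = 0.00397). pi-Eif4ebp2.1, over the gene for a translation repressor (chromosome 10, 61428491 to 61452798, minus strand), rose from 2131 ± 87.0 to 5453 ± 651 CPM, 1-qD-2017.2 from 3891 ± 161 to 9942 ± 1587 CPM and 19-qC2-1361.2 from 3150 ± 134 to 7678 ± 760 CPM (log2 fold changes 1.36 ± 0.12, 1.35 ± 0.13 and 1.28 ± 0.10). The 2 loci that fell were 9-qF4-150.2 (-0.49 ± 0.08, adjusted p = 0.0224, edgeR quasi-likelihood) and the abundant 5-qG3-23659.2 (11422 ± 690 to 8672 ± 108 CPM, -0.40 ± 0.08, adjusted p = 0.0446). Smaller rises were seen at 8-qA4-332.2 (0.92 ± 0.15), pi-1700006A11Rik.2 (0.74 ± 0.08), 1-qE3-706.1 (0.70 ± 0.09), 4-qD3-2082.1 (0.64 ± 0.07), 13-qA3.1-355.1 (0.59 ± 0.09) and 15-qE1-3710.1 (0.57 ± 0.09). The other 4 that rose, named here after their values were seen, were pi-Ip6k1.2 (0.52 ± 0.09), pi-Luzp1.1 (0.52 ± 0.08), 11-qB1.3-590.3 (0.43 ± 0.09) and 4-qB3-639.1 (0.42 ± 0.08).

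The number of precursor calls depended on single libraries. Without Exd2∆ replicate 1, whose correlation with replicate 2 (r = 0.986 across loci) was close to the highest between genotypes (0.985), 60 loci were called (35 higher, 25 lower), without Exd2∆ replicate 2, 105 (56 higher, 49 lower), and without either Exd2+/+ replicate 0 (edgeR quasi-likelihood), with 17 and 20 loci at an unadjusted p under 0.05, 5 and 5 called by edgeR's exact test, 8 and 9 by DESeq2 and 0 and 0 by limma-voom. All 16 kept their direction in each of these fits. Where both Exd2∆ libraries lie on 1 side of both Exd2+/+ libraries, leaving out 1 library can hardly turn the sign, so this is no separate support. At scaling to the library total 11-qB1.3-590.3 and 4-qB3-639.1 were not called (adjusted p = 0.0684 and 0.0699, edgeR quasi-likelihood), and with edgeR's default option 11-qB1.3-590.3 and 5-qG3-23659.2 were not (adjusted p = 0.0515 each).

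Of the 10 precursors with the highest mean CPM over all 4 libraries, 1 was called, 17-qC-935.1, which ranks among them only through its own rise. 17-qA3.3-26735.1 (-0.23 ± 0.09), 9-qC-31469.1 (-0.26 ± 0.08), 7-qD2-24830.3 (-0.34 ± 0.10), 12-qE-23911.2 (-0.20 ± 0.08) and 2-qE1-35981.2 (-0.12 ± 0.09) stood below 0, and 6-qF3-8009.1 (0.14 ± 0.08), 13-qB1-1517.1 (0.05 ± 0.08) and pi-1700016M24Rik.2 (0.39 ± 0.10) above (lowest adjusted p = 0.0836, edgeR quasi-likelihood). 13-qB1-1517.1 turned to -0.01 at scaling to the library total. 7-qD1-19431.2 stood at -0.06 ± 0.11 and turned to 0.08 without Exd2∆ replicate 1. Of less abundant loci, pi-Socs7.1 stood at 0.49 ± 0.16 (adjusted p = 0.125, edgeR quasi-likelihood), and 4-qC5-17839.1 (-0.46 ± 0.11), 3-qA2-617.1 (-0.77 ± 0.18) and pi-Lsmd1.1 (1.07 ± 0.26) missed the threshold (adjusted p = 0.0722, 0.0644 and 0.0722). The neighbouring loci 14-qC1-1261.1 (5940 ± 411 to 3437 ± 1960 CPM) and 14-qC1-1010.2 (4687 ± 534 to 2981 ± 1734 CPM; SD, n = 2 each) differed widely between the Exd2∆ replicates (adjusted p = 0.243 and 0.325).

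As a group, the listed precursors were lower relative to the other loci in long RNA. Their mean log2 fold change was 0.28 below that of the rest (mean of the listed loci minus the rest -0.28, camera adjusted p = 3.71e-04 with a preset correlation, adjusted p = 0.927 with an estimated correlation), and 29 of the 35 had a negative value. By edgeR quasi-likelihood 0 of the 35 passed, over all loci or adjusted over the list alone, with 13 at an unadjusted p under 0.05, 5 called by DESeq2, 2 by edgeR's exact test and 1 by limma-voom, all lower. Their share of the long RNA counts was 37.0% ± 0.606 in Exd2+/+ and 31.4% ± 1.62 in Exd2∆ (SD, n = 2 each). Gene-named loci were higher than band-named loci by 0.15 on average (camera adjusted p = 0.0117 with a preset correlation, adjusted p = 0.927 with an estimated correlation), although only 4 of 114 gene-named loci were called, all higher, against 10 higher and 2 lower of the 94 band-named loci. Adjusted over the list alone, the counts were 4 higher of the gene-named loci, and 11 higher and 5 lower of the band-named loci. The listed loci are all band-named, with a mean of -0.18 against -0.03 over all band-named loci. The medians lay closer, at -0.15 and -0.12, and 65 of the 94 band-named loci had a negative value. How far the listed loci stand apart from band-named loci therefore depends on the summary. The 2 comparisons therefore overlap and are not separate findings. The gene-named call was lost without Exd2∆ replicate 1 (0.06, adjusted p = 0.513), while the listed loci stayed lower (-0.19, adjusted p = 0.00547). The fry test called 0 of the 21 groups for movement in 1 direction and 1 for change in either direction. At scaling to the library total the median log2 fold change over all loci was -0.04 (-0.07 to -0.03 over the 4 library pairs), and with TMM, used for all other fold changes, it turned to 0.02.

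Where both assays called a locus, piRNAs and precursors mostly moved in opposite directions. Of the 14 loci with more precursor in Exd2∆, 12 had fewer piRNAs, against 4.44 for independent lists (Fisher's exact test, two-sided p = 2.51e-05, adjusted p = 1.00e-04 over 4 combinations of direction). That test takes loci as independent units, although all calls rest on the same 2 libraries per genotype and assay. Seen from the other side, 54 of the 66 loci with fewer piRNAs were not called in long RNA, against 192 of all 208 loci. Among them were pi-Fam53b.1 (0.07 ± 0.09 in long RNA) and 13-qA5-967.1 (-0.06 ± 0.12). The median long RNA log2 fold change of the 66 was 0.09, against -0.09 for the 69 loci with more piRNAs. At 17-qC-935.1 piRNAs fell 4.22-fold while precursor rose 4.03-fold. At 1-qD-2017.2 (chromosome 1, 91403055 to 91406029, minus strand, 38.7% of its span within the lincRNA gene 1700020N18Rik) the log2 fold change was -1.28 ± 0.06 in small and 1.35 ± 0.13 in long RNA, and at pi-Eif4ebp2.1 it was -1.24 ± 0.08 and 1.36 ± 0.12. At 4-qD3-2082.1, within the lincRNA gene 1700029M20Rik, it was -1.10 ± 0.06 and 0.64 ± 0.07. 9-qF4-150.2 went the other way (0.67 ± 0.10 in small RNA, -0.49 ± 0.08 in long RNA), and 19-qC2-1361.2 was higher in both. pi-Luzp1.1 was higher in long RNA and not called in small RNA (-0.16 ± 0.13, adjusted p = 0.314, edgeR quasi-likelihood).

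The genotype effect differed between the assays at 108 loci, 53 with a higher and 55 with a lower fold change in small than in long RNA (interaction of assay and genotype over all 8 libraries, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). All 12 loci with fewer piRNAs and more precursor were among them. They were chosen for opposite calls in these same libraries, which nearly fixes this outcome, so it is no separate support. Without either Exd2+/+ long RNA library no locus was called higher in long RNA, so the count of 12 became 0, and it was 20 and 30 without Exd2∆ replicate 1 or 2 of the long RNA. The directions held at all 12 loci in each of these fits. Leaving out 1 library could hardly turn them, since both Exd2∆ libraries lie on 1 side of both Exd2+/+ libraries there.

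**Figure D2:**
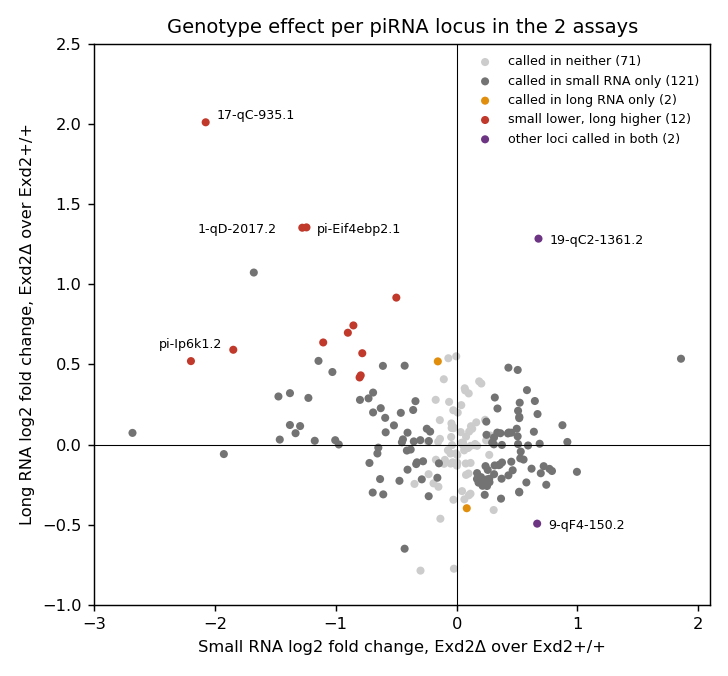
Log2 fold change of Exd2∆ over Exd2+/+ in long RNA (vertical axis) against that in small RNA (horizontal axis) for the 208 piRNA loci. Each point is a locus, coloured by the assays in which it was called at an adjusted p below 0.05. The 12 red loci had fewer piRNAs and more precursor in Exd2∆, with 17-qC-935.1 farthest out at -2.08 and 2.01.

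Across all 208 loci the fold changes of the assays ran against each other. The correlation was negative (Pearson's r = -0.37, permutation p = 1e-05, adjusted p = 4e-05; Spearman's rho = -0.27, permutation p = 1e-04, adjusted p = 3.4e-04), and r was -0.37 without the 2 loci farthest from the median in small RNA. For each of the 16 combinations of library pairs rho lay between -0.33 and -0.19. It was stronger in value among the 94 band-named loci (r = -0.52, rho = -0.39) than among the 114 gene-named loci (r = -0.30, rho = -0.24), a difference that was not tested. Among the 35 listed loci r was 0.32 (permutation p = 0.0638). These 4 correlations are across loci, which are not independent replicates, and 1e-05 is the smallest p that 100000 permutations can give.

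**Figure D3:**
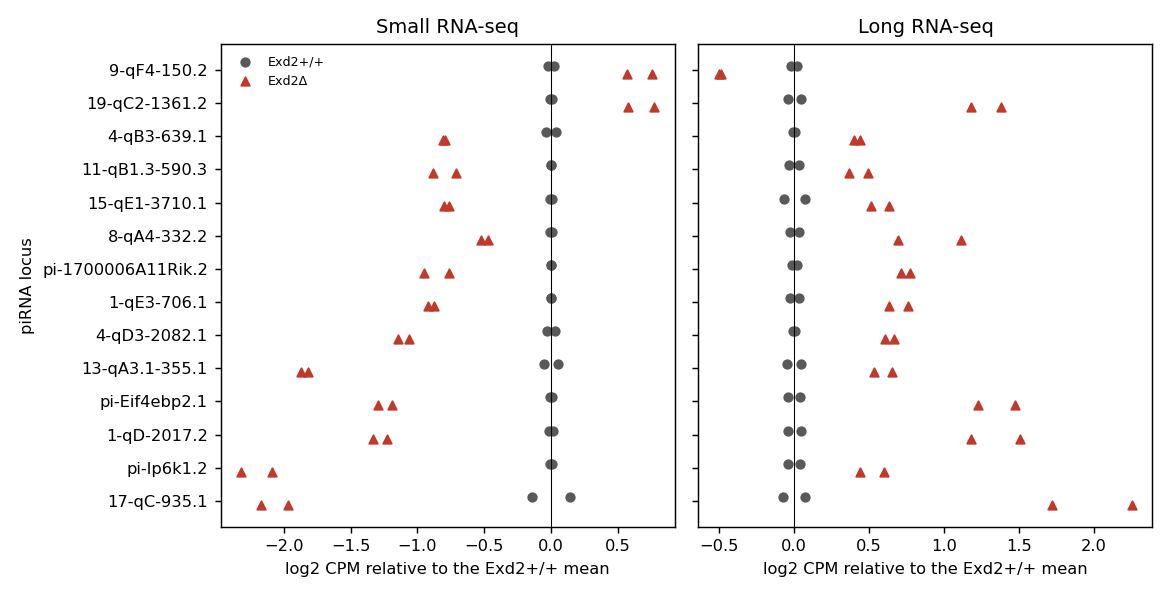
Log2 CPM of each library relative to the Exd2+/+ mean (horizontal axis) at the 14 loci called in both assays (vertical axis), in small RNA (left) and long RNA (right). Grey circles are the 2 Exd2+/+ and red triangles the 2 Exd2∆ libraries of each assay. At 12 loci both Exd2∆ libraries lie below both Exd2+/+ libraries in small RNA and above them in long RNA.

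The authors' deposited table gives 137 loci with an adjusted p below 0.05 in small RNA (70 higher, 67 lower) and 18 in long RNA (14 higher, 4 lower). Of these, 134 and 16 were called here too, each in the same direction. The direction of the authors' fold changes was taken from the values. Both results rest on edgeR and the same counts, so the match is no separate support. The authors' deposited table and the present fits differed by at most 0.04 in log2 fold change in small RNA and 0.17 in long RNA.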

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

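The tests of counting depth, of the size of fold changes in both assays and of trends with locus properties were chosen before their results were seen, and the other tests of this part, as well as the count of loci with opposite changes, were chosen after.

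The genotype effect differed between small and long RNA at 108 loci (interaction term, edgeR quasi-likelihood, adjusted p below 0.05). The difference in log2 fold change, small minus long, was -4.09 at 17-qC-935.1, -2.72 at pi-Ip6k1.2, -2.63 at 1-qD-2017.2, -2.60 at pi-Eif4ebp2.1 and -2.44 at 13-qA3.1-355.1. It was -1.74 at 4-qD3-2082.1, -1.60 at both pi-1700006A11Rik.2 and 1-qE3-706.1, -1.42 at 8-qA4-332.2, -1.35 at 15-qE1-3710.1, -1.23 at 11-qB1.3-590.3 and -1.22 at 4-qB3-639.1. At 9-qF4-150.2 it was 1.16, the opposite direction.

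At the 12 loci with fewer piRNAs and more precursor in Exd2∆, a candidate explanation is that less of the precursor was turned into piRNA. Trends with locus length, abundance, exonic share or name class do not account for the whole of the opposite signs, since 12 of 12 loci kept both after regression on these, 10 of them by more than 2 SE in both assays, and over all loci rho between the assays was -0.26 after regression against -0.27 before. The R² of the regression was 0.388 in long and 0.0863 in small RNA, and the smallest long RNA value of the 12 was 0.42 before and 0.12 after, so at the other 2 loci they stay open. The 12 were chosen for opposite calls in the same data, and trends as weak as those in small RNA could hardly turn their small RNA signs. Less processing was not tested apart from the pattern that prompted it. This explanation, a rise of mRNA rather than precursor at the loci over protein-coding genes (pi-Ip6k1.2, pi-Eif4ebp2.1, pi-1700006A11Rik.2, 11-qB1.3-590.3 and 4-qB3-639.1), more transcription together with less processing, a change in the share of cells at each stage of spermatogenesis, and library preparation stay open, as the design has 2 replicates per genotype and assay and no markers were analysed. At 4-qB3-639.1 only 2.2% of the span is exonic, so mature mRNA could cover little of that locus.

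Many more loci were called in small than in long RNA (135 and 16). Depth alone does not account for this: after thinning the small RNA counts to the long RNA totals a median of 111 loci was still called (103 to 123 over 20 draws). Less spread between small RNA replicates is not the whole difference either, as the median absolute log2 fold change was 2.06 times that of long RNA (1.61 to 2.85 with any library left out). Spread between the long RNA Exd2∆ libraries stays open as a large part of it: without Exd2∆ replicate 1 or 2, 60 and 105 loci were called in long against 123 and 123 in small RNA (ratios 0.488 and 0.854), though the remaining library's own deviation then counts as a genotype difference. Small RNA libraries of a genotype resembled each other more than those of the other genotype (lowest r within minus highest r between 0.0116), which a batch shared with genotype would also give, so batch and genotype cannot be told apart.

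The long RNA log2 fold change fell with locus length (rho = -0.28 across loci, permutation p = 5e-05) while the small RNA one rose (rho = 0.15, permutation p = 0.0356, adjusted p = 0.0427 over 6 relations), and the 12 loci with opposite changes were short, with a median of 8181 bp against 30891 bp for the rest (permutation p = 1.1e-04). The 12 were chosen in part for a long RNA rise, so their shortness is not separate from the long RNA trend. They were also more abundant, with a median of 1407 against 261 CPM in Exd2+/+ small RNA. Whether Exd2∆ replicate 1 is the only source of the long RNA trend cannot be told: replicate 2 against the Exd2+/+ mean gave rho = -0.15 (permutation p = 0.0296, adjusted p = 0.0427), but its Pearson's r of -0.25 is near the -0.22 between the Exd2+/+ replicates. The Exd2∆ replicates differed from each other along length too (rho = -0.33, permutation p = 1e-05, the smallest the permutations can give). A difference in RNA integrity or fragment size between long RNA libraries could give part of the trend in this way. The Exd2+/+ replicates differed along length by Pearson's r (permutation p = 0.00214) but not by rank (rho = -0.03, permutation p = 0.714). A few loci can set such an r, so it is a weak sign of a trend and a weak yardstick for replicate 2. The mean of the listed precursors lay 0.27 below the rest at equal length, against 0.28 without that correction, and that of the gene-named loci 0.24 above the band-named ones, against 0.15 (at equal length 0.36 and 0.19 below, and 0.36 and 0.11 above, with Exd2∆ replicate 1 or 2 alone). A biological effect of genotype on long precursors stays untested.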

How the results depend on the processing

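The legacy and default options of edgeR, the replicate block and voom weights for the interaction, and all settings of the count of opposite loci were chosen after the data were seen; alternatives for normalized values were not run. The small RNA calls (135) stayed between 101 and 148 except with an absolute log2 fold change above 1 (21, by construction), and 101 to 123 with 1 library left out. The long RNA calls (16) became 39 with DESeq2 (28 higher, 11 lower), 25 with the exact test (20 and 5), 26 at an adjusted p below 0.1, 4 with an absolute log2 fold change above 1, and 0 to 105 with 1 library left out, where a lone library is assumed to vary like the other group. The opposite loci (12) numbered 0 to 30 with 1 library left out and 10 to 18 otherwise; the interaction calls (108) 80 to 129. The median log2 fold change moved in small RNA to 0.039 with TMM, 0.0073 with RLE and 0.0426 to 0.102 with 1 library left out, and in long RNA to 0.015 with TMM and 0.013 with RLE (-0.067 to -0.037 with 1 left out). In long RNA camera called 3 of the 21 groups with the preset correlation and 0 with an estimated correlation. The cause of these shifts was not tested.

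The replicate block gave 118 small RNA calls (without 12-qE-23911.2 and 14-qA3-19970.2, adjusted p = 0.131 and 0.0522) and 38 long RNA calls (27 higher, 11 lower). Replicate numbers were not taken as pairing, since the labels do not tie the same numbers together. The r of the deviations of same-numbered libraries was 0.0393 in small and 0.342 in long RNA, so a shared preparation of same-numbered long RNA libraries stays possible.

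The text names 47 loci in small and 31 in long RNA, the 39 and 27 of the rule with 8 and 4 added after the values were seen. Of these 38 and 16 were called, and 0 changed sign under any setting. Where both Exd2∆ libraries lie on 1 side of both Exd2+/+ libraries, leaving out 1 library can hardly turn a sign. Apart from the other thresholds on adjusted p and fold change, which were run on the counts of calls only, in small RNA 2 lost the call under some setting, and in long RNA all 16 (3 of them also other than by leaving out a library), while 8 and 14 uncalled ones gained one. Some uncalled ones changed sign. With 1 library left out, small RNA values ranged from -0.187 to 0.0622 at 2-qE1-35981.2, -0.0108 to 0.122 at 6-qF3-28913.1, -0.0349 to 0.180 at 5-qG3-23659.2, -0.113 to 0.0408 at 7-qD2-24830.3, -0.0669 to 0.196 at 9-qA5.3-24188.1 and -0.0131 to 0.226 at pi-Tmem194.3, and long RNA values from -0.194 to 0.0765 at 7-qD1-19431.2. At library-total scaling 7-qD2-24830.3 was 0.0176 in small and 13-qB1-1517.1 -0.0125 in long RNA. Simulations drew loci independently with each assay's own depth and 1 dispersion per locus for both genotypes. They recovered 29.5% of the smallest changes in long RNA against 64.0% in small RNA.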

Other observations

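The tests of neighbouring loci were chosen after the fold changes were seen.

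In small RNA fry called 6 chromosomes for movement in 1 direction, chromosome 9 upward and chromosomes 5, 6, 13, 15 and 17 downward (adjusted p = 0.0386 to 0.0495). On chromosome 9, 9 of 15 loci had more piRNAs in Exd2∆ and 2 had fewer, and on chromosome 15, 2 had more and 8 fewer of 13. On chromosome 13, 2 had more and 6 fewer of 11, among them 13-qA5-967.1, 13-qA3.1-355.1, pi-Zfp346.2 and pi-Hist1h1a.2. On chromosome 5, 1 had more and 5 fewer of 14, on chromosome 6, 5 had more and 7 fewer of 15, and on chromosome 17, 1 had more and 4 fewer of 8. On chromosome 6 the median log2 fold change was 0.06 and the mean -0.27, so its direction depends on the summary. Fry tests balance within a chromosome, while camera, which compares it with the other loci, called 0 of the 6 (lowest adjusted p = 0.379 with a preset correlation, at chromosome 13, and 0.913 with an estimated correlation).

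Of the 208 loci, 12 pairs are divergent, with starts within 2000 bp on opposite strands and so perhaps a shared promoter. If a promoter set the change, partners should move together in small RNA. They shared a sign in 4 of 12 pairs, with rho = -0.24 over the pairs (permutation p = 0.456), too few pairs to exclude a shared change. In long RNA 9 of the 12 pairs shared a sign (rho = -0.18, permutation p = 0.574). Many partners are listed loci, and 29 of the 35 listed loci were negative in long RNA, so these shared signs say little about a shared promoter.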
